A study of Mus musculus with 9 samples.

How the data were processed

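ATAC-seq peak lists of 9 libraries were analysed: untreated B16 melanoma cells, B16 cells exposed to interferon gamma and the resistant line Res499, with 3 libraries each. Per the submitters' processing notes, the tools were CASAVA, cutadapt 1.9, Bowtie2 2.2.4 and MACS2, and the genome build was GRCm38 (mm10). The MACS2 version, its settings and any shift of reads for the transposase were not given in the sources used here. If reads were not shifted, peak edges would move by a few bases, which is small beside a median region width of 677 bp.

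Each deposited file is a list of peaks in a 10-column format, called separately for each library and not on pooled replicates. The deposited values per peak are positions, a score, the fold enrichment over the local background (a ratio), and the −log10 p and −log10 q of the caller. These values are the authors' and were used here only to describe, rank and filter peaks within a list and to recover depth. The lowest −log10 q in the deposited lists is close to 2 in each library.

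The lists carry no read counts. The fold and the −log10 p of a peak together fix its whole summit pileup and the local background, and 99.99% to 100% of the peaks of a library with a −log10 p under 200, after rounding, were recovered within 0.01. The lowest background, divided by the shortest peak width, gave the relative depth in fragments per kb of the effective genome, whose size was not given in the sources used here, so reads per library are not stated. Shortest peaks of at least 150 bp marked the long fragment class (B16_untreated replicates 1 and 3, B16_IFNg replicate 3 and Res499 replicate 3) and the others the short class. This class was treated as a technical batch. Where a class holds 1 library of a group, values are given without a test.

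Lists of unequal length cannot be compared by presence, so the 9214 most significant peaks on chromosomes 1 to 19, X and Y were kept in each library, the length of the shortest list. Peaks that overlapped or touched were merged into regions, and a region was called in a library with at least 1 overlapping base. Gained and lost regions were those called in every library of one group and in none of the other. A 3-against-3 exact test cannot go below p = 0.1, so no p was given per region, and the smallest p for 3 of 9 libraries is 0.0119. Group values were compared by two-sided exact permutation tests, except the test of group similarity, which was one-sided. Shares of regions were compared by two-sided Fisher's exact tests, with regions called in at least 3 libraries of the comparison as background. Benjamini-Hochberg adjustment was made over lists, or over chromosomes, directions and comparisons.

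Gene positions came from a RefSeq gene table of GRCm38.p6, the build of the files, which was checked by the share of peaks near coding gene ends (65.9% to 72.3%) against the same peaks moved by 50000 bp (8.06% to 9.39%). The table gives no strand and no exons. The planned distance to transcription starts was therefore replaced by the distance to either annotated end of a gene, and exons, introns and UTRs are not given. An annotated end may lie away from the main start in use. Each region was assigned to the nearest coding gene end within 50000 bp. No genome sequence was used here, so the planned search for 14 motifs was not run.

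The lists of genes, the alternatives and the rule for named genes were fixed before the data were examined. The rule names 13 genes always, up to 20 list genes nearest a gained or lost region per comparison, and the 10 gained and 10 lost regions with the best mean rank. The text gives the leading part of these, and 1 of the genes is not reported here. Of the list names, 1 had no match in the gene table. The calling of gained and lost regions was tested on simulated calls with 200 changed regions per comparison, called at rates of 95% or 5%. For B16_IFNg against B16_untreated, with 14042 regions, 70% of planted gains and 68% of planted losses were recovered where the call rates allow 73.5%, and 129 unchanged regions were called. For both groups together, with 15643 regions, 60% and 54% were recovered where 63.0% is possible, and 14 unchanged regions were called. The strict rule therefore misses real changes, and with 3 libraries per group a large part of its calls can be chance.

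Alternatives used all deposited peaks, 4607 peaks per library, a peak covering 50% of the region, merging of peaks up to 250 bp apart, a lenient rule allowing 1 missing library, absence from the full lists of the other group, windows of 2.5 kb, gene assignment within 10 kb, the replicate number as a block, and each library left out. Ranking by fold enrichment, leaving out Res499 replicate 2 with longer lists, all alternatives for the position of gained and lost regions, and ranking by fold enrichment or leaving out libraries in the chromosome tests were added after seeing the data. Peaks on chromosome M (2 to 12 per library) and on unplaced sequence were left out. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.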

Results

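Open chromatin was profiled by ATAC-seq, in which a transposase cuts and tags accessible DNA, in cells of the mouse melanoma line B16. The cells were sorted from tumours harvested on day 15. The 9 libraries formed 3 groups of 3: untreated B16 cells (B16_untreated), B16 cells after chronic exposure to interferon gamma (B16_IFNg), and Res499, a line derived from B16 that resists immune checkpoint blockade. The labels give 2 weeks of interferon for B16_IFNg replicates 1 and 2 and 3 weeks for replicate 3. Nothing in the labels says whether replicates came from separate mice, so p-values measure only the spread between these libraries.

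The untreated cells had the most called accessible regions. B16_untreated had 20186 ± 5165 peaks (SD, n = 3), B16_IFNg had 13533 ± 2547 (SD, n = 3) and Res499 had 12128 ± 3103 (SD, n = 3). The peaks of B16_untreated covered 10.01 ± 1.74 Mb (SD, n = 3) of the genome, against 5.69 ± 1.09 Mb (SD, n = 3) in B16_IFNg and 5.02 ± 1.28 Mb (SD, n = 3) in Res499. With B16_IFNg and Res499 pooled, the number of peaks was 0.636 times that of B16_untreated (two-sided exact permutation test over 84 choices, p = 0.0357). The covered length was 0.535 times (exact p = 0.0119, the smallest these 9 libraries can give). In an exact test single pairs of groups cannot go below p = 0.1. The exact p for peak number was 0.2 for B16_IFNg, 0.2 for Res499 against B16_untreated and 0.6 between B16_IFNg and Res499. The call on peak number was lost without B16_untreated replicate 2 (exact p = 0.143), B16_untreated replicate 3 (exact p = 0.107), Res499 replicate 2 (exact p = 0.0536), and B16_IFNg replicate 2, B16_IFNg replicate 3 or Res499 replicate 3 (exact p = 0.0714 for each).

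The relative depth, in fragments per kb of the effective genome, was 9.58 ± 1.35 (SD, n = 3) in B16_untreated, 8.19 ± 0.851 (SD, n = 3) in B16_IFNg and 10.2 ± 1.37 (SD, n = 3) in Res499, and the exact p for B16_IFNg and Res499 together against B16_untreated was 0.726. The libraries also fell into a long and a short class by the fragment length that the caller used, read from the shortest peak of each list. In the long class, the lists held 15045 and 20139 peaks in B16_untreated, 11183 in B16_IFNg and 11768 in Res499. In the short class they held 25374 in B16_untreated, 16240 and 13175 in B16_IFNg, and 15396 and 9221 in Res499. Within the classes, B16_untreated had on average 8991 more peaks than the other groups (two-sided exact permutation test over 30 arrangements, p = 0.0333).

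**Figure D1:**
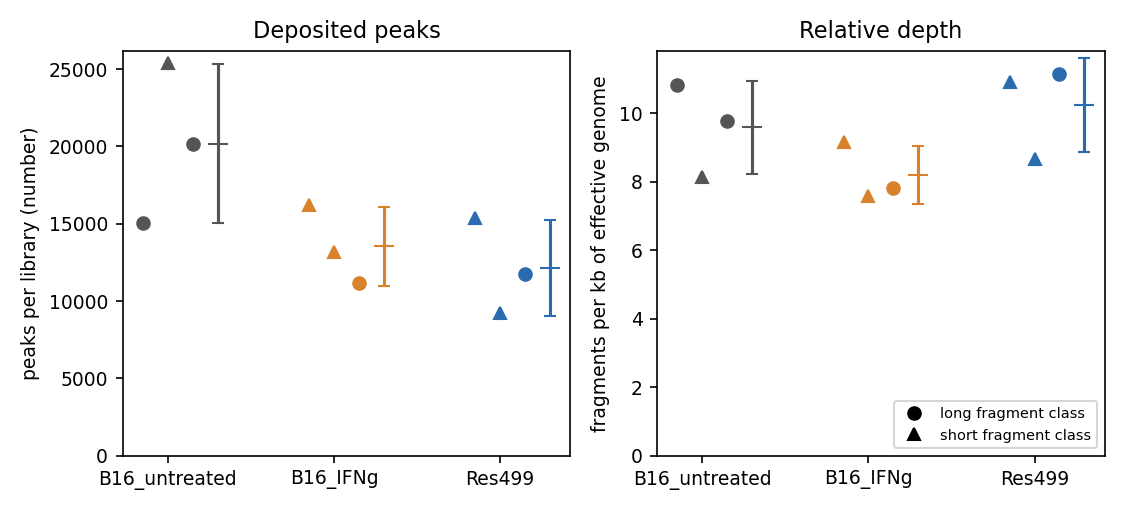
Deposited peaks per library (left, number) and relative depth (right, fragments per kb of effective genome) in each group of 3 libraries. Circles and triangles mark the long and short fragment class, and bars show the mean and SD beside the points. Peak numbers run from 9221 to 25374, and the Res499 libraries lie between 8.68 and 11.1 in depth.

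Because list lengths differed, regions were compared over the 9214 most significant peaks of each library. These merged into 15643 regions, of which 4486 were called in all 9 libraries and 3409 in 1 library only. Sites near gene ends dominated. Such peaks, within 1 kb of an end of a protein-coding gene, made up 67.0 ± 1.01% in B16_untreated (SD, n = 3), 69.5 ± 2.52% in B16_IFNg (SD, n = 3) and 70.2 ± 1.88% in Res499 (SD, n = 3). The difference of 2.90 percentage points between B16_IFNg with Res499 and B16_untreated had an exact p of 0.0714, and within the fragment classes it was 2.31 points (exact p = 0.1). That difference passed the threshold in lists ranked by fold enrichment, at 4.15 points (exact p = 0.0357), and without B16_IFNg replicate 3, at 3.55 points (exact p = 0.0357). It was 14.4 points over all deposited peaks (exact p = 0.0119), where list lengths differ between groups, so that value is not a like comparison. The mean Jaccard index was 0.642 between libraries of one group and 0.633 between libraries of different groups. The difference of 0.00892 was one that 20 of the 280 partitions of the libraries matched (one-sided exact p = 0.0714). Without Res499 replicate 3 that difference was 0.0153 (exact p = 0.0429), and without B16_untreated replicate 3 it was -0.00141 (exact p = 0.568). Libraries of one fragment class had a mean index of 0.639 and libraries of different classes 0.632. The mean index of Res499 was 0.627 with B16_IFNg and 0.624 with B16_untreated (two-sided exact p = 0.6, where 0.1 is the smallest possible).

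The comparison of B16_IFNg with B16_untreated asks which regions open or close in tumour cells after long exposure to interferon gamma. Coordinates are those of GRCm38. Called in all 3 B16_IFNg libraries and in none of B16_untreated (gained) were 60 regions, and the opposite pattern (lost) was seen at 86. Gained regions included the ends of Adsl, an enzyme of purine synthesis (chromosome 15, 80948201 to 80948764), and Limd1 (chromosome 9, 123478289 to 123479084). Another was at the end of Sox9, a transcription factor of the neural crest (chromosome 11, 112782024 to 112782893). Others lay inside Hectd4, 565 bp from its end (chromosome 5, 121220078 to 121220700), and inside Slc6a9, a glycine transporter, 705 bp from its end (chromosome 4, 117835963 to 117836743). Lost regions included the ends of Atad3a (chromosome 4, 155760684 to 155761294), Hmgb3 (chromosome X, 71555623 to 71556928) and Fbxo46 (chromosome 7, 19119632 to 19120273). The ends of Chgb (chromosome 2, 132781548 to 132781957) and Tbp, the TATA-binding protein (chromosome 17, 15499596 to 15500223), were lost too. A region inside Psmb10, a subunit of the immunoproteasome, 849 bp from its end (chromosome 8, 105936891 to 105937543), was also lost. A site 20676 bp from Lcp2, a leukocyte signalling adaptor (chromosome 11, 34112957 to 34113475), was called in all B16_untreated libraries and in none of the other 6. In the full lists 59 of the 60 gained regions had a peak in B16_untreated and 69 of the 86 lost ones had a peak in B16_IFNg, ranked below the 9214 used. The Adsl, Limd1, Sox9, Hectd4 and Slc6a9 regions had one there in all 3 B16_untreated libraries. The Atad3a, Tbp and Psmb10 regions had one in 2 B16_IFNg libraries, the Hmgb3, Fbxo46 and Chgb regions in 1 and the Lcp2 site in 0 B16_IFNg and 1 Res499 libraries.

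Gained and lost regions of this comparison differed in position, a test chosen after the data were seen. Of the gained regions, 68.3% lay within 1 kb of a coding gene end, against 29.1% of the lost ones (Fisher's exact test over regions, p = 3.87e-06), with 70.6% among background regions. Regions are not replicates, and the p describes these libraries. In the short fragment class the shares were 70.0% of gained and 24.5% of lost regions. In the long class, with 1 B16_IFNg library, they were 38.7% and 56.0%. There a gained region needs 1 call and a lost one 2, and in the short class the reverse holds. In each class the side that needs 1 call had the lower share. These shares therefore cannot show whether the relation holds within classes. The B16_IFNg library of the long class is also the only one labelled 3 weeks, so class and weeks of exposure cannot be told apart within B16_IFNg. Over all deposited peaks the shares were 20% and 13.0% (Fisher's exact p = 0.503). With lists of 4607 peaks they were 81.4% and 63.0% (Fisher's exact p = 0.0704). The gap of 39.3 points fell to 12.7 without B16_IFNg replicate 1 (Fisher's exact p = 0.0185) and to 19.4 without B16_IFNg replicate 2 (Fisher's exact p = 0.000956). With either left out, a gained region needs fewer calls than a lost one, so these falls cannot be told apart from that change in the rule. The gained and lost regions made up 10.97% of the 1331 regions called in exactly 3 of these 6 libraries, where chance gives 10%. Over all deposited peaks, where the untreated lists are longer, 5 regions were gained and 771 lost.

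Res499 against B16_untreated addresses what distinguishes the resistant line. Here 86 regions were gained and 142 lost, 17.3% of the 1320 regions called in exactly 3 of the 6 libraries. Gained regions lay at the ends of Wipf2 (chromosome 11, 98863419 to 98863946) and the ribosomal protein gene Rpl26 (chromosome 11, 68901240 to 68901976). Others lay at the ends of the kinase genes Rps6ka1 (chromosome 4, 133887590 to 133888313) and Plk3 (chromosome 4, 117133541 to 117134169), and Ccdc32 (chromosome 2, 119029199 to 119029679). A region inside Sp140, 3707 bp from an end of the interferon-stimulated gene Sp110 (chromosome 1, 85614557 to 85614831), was called in 3 Res499, 2 B16_IFNg and 0 B16_untreated libraries. Lost regions included the end of Tyrp1, an enzyme of melanin synthesis (chromosome 4, 80834091 to 80834718), and the end of Ccn2, a matricellular growth factor (chromosome 10, 24595313 to 24596102). The end of the glycolytic gene Gpi1 (chromosome 7, 34229859 to 34230458) and a site 873 bp from Bcl3, a regulator of NF-kB (chromosome 7, 19823697 to 19824462), were lost as well. More distant lost sites lay inside Padi2 (chromosome 4, 140929719 to 140930533) and 13023 bp from Cyp24a1, which degrades vitamin D (chromosome 2, 170469619 to 170469934). A further site lay 28358 bp from Spred1, an inhibitor of Ras signalling (chromosome 2, 117210637 to 117211191). In the full lists 83 of the 86 gained regions had a peak in B16_untreated and 98 of the 142 lost ones had a peak in Res499. The Wipf2, Rpl26, Rps6ka1, Plk3 and Ccdc32 regions had one in 3 B16_untreated libraries and the Sp140 region in 1. The Tyrp1, Ccn2, Gpi1, Padi2 and Cyp24a1 regions had one in 1 Res499 library, and those of Bcl3 and Spred1 in 0.

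Gained regions of Res499 lay near coding gene ends in 77.9% of cases and lost regions in 31.0% (Fisher's exact test over regions, p = 3.70e-12), with 71.6% in the background. In the short fragment class these shares were 70.0% and 28.3%. In the long class, with 1 Res499 library, they were 45.0% and 51.2%. Here too the side that needs 1 call, gained in the long class and lost in the short, had the lower share. Whether the relation holds within classes cannot be told from these values. The gap of 46.9 points was 17.4 without Res499 replicate 1 (62.0% and 44.6%, Fisher's exact p = 0.000202). A gained region then needs fewer calls than a lost one, and the fall cannot be told apart from that change in the rule. Over all deposited peaks the counts were 8 gained and 1210 lost, with 50% and 19.3% near gene ends (Fisher's exact p = 0.0509). Without Res499 replicate 2, whose list was the shortest, and with lists of 11181 peaks, 209 regions were gained and 288 lost.

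Chromosome X held 9 of the 142 lost regions of Res499, or 6.34%, against 1.30% of background regions (Fisher's exact test, adjusted p = 0.0122 by Benjamini-Hochberg over 168 tests). The Txlng region (chromosome X, 162829232 to 162829700) and the Enox2 region (chromosome X, 49287823 to 49288500) were called in all B16_untreated libraries and in no Res499 library, though in the full lists they had a peak in 2 and 1 Res499 libraries. The other 7, chosen after their values were seen, lay at the ends of Rp2, Cetn2, Nono (an RNA-binding protein of paraspeckles), Pdha1 (a subunit of pyruvate dehydrogenase), Aifm1, Mpp1 and Naa10. Against B16_IFNg, 8 of the 84 lost regions were on chromosome X, 9.52% against 1.22% of background (Fisher's exact test, adjusted p = 0.00202). Enox2, Cetn2, Nono, Pdha1 and Aifm1 were among them in both comparisons. Peaks on X made up 1.11% of the used peaks of Res499 in the long class, against 1.31% and 1.48% in B16_untreated and 1.32% in B16_IFNg. In the short class they made up 1.09% and 0.955% in Res499, against 1.96% in B16_untreated and 1.48% and 1.68% in B16_IFNg. No other chromosome passed the adjusted threshold in these lists, while 9 of the 168 tests had an unadjusted p under 0.05. Others passed under other settings. With all deposited peaks, chromosome 19 held 4.96% of the regions lost in Res499 against B16_untreated (background 2.80%, Fisher's exact test, adjusted p = 0.0152), and chromosome 7 held 15.3% of those lost against B16_IFNg (background 6.89%, adjusted p = 0.0473). Chromosome 5 held 10.9% of the regions gained in Res499 against B16_untreated under the lenient rule (background 6.01%, Fisher's exact test, adjusted p = 0.00376) and 13.7% without B16_untreated replicate 1 (background 5.86%, adjusted p = 0.00136). It also passed for gains of B16_IFNg without B16_IFNg replicate 3 (12.3% against 5.64%, Fisher's exact test, adjusted p = 0.0257) and, with a low share, for losses of Res499 against B16_IFNg without B16_IFNg replicate 1 (1.01% against 6.22%, adjusted p = 0.0424). Chromosome 11 passed for gains of Res499 against B16_untreated without Res499 replicate 3 (14.7% against 7.73%, Fisher's exact test, adjusted p = 0.0192). Under the lenient rule chromosome 18 passed for losses of Res499 against B16_untreated (4.24% against 2.07%, Fisher's exact test, adjusted p = 0.0396). There chromosome 5 held fewer lost regions of Res499 than the background, 2.77% against 6.09% for B16_untreated and 2.51% against 6.28% for B16_IFNg, and more regions gained in both groups together, 17.9% against 5.95%. The X call was not reached over all deposited peaks, with 2.64% of lost regions against 1.69% of background for Res499 against B16_untreated (Fisher's exact test, adjusted p = 0.461) and 4.38% against 1.69% for Res499 against B16_IFNg (adjusted p = 0.520). Both X calls held under the lenient rule, at 4.89% and 5.65%. They also held without each library of their own comparison in turn, which lowers the number of calls needed. The second share was then 5.18% without Res499 replicate 1, 5.37% without B16_IFNg replicate 2 and 6.25% without Res499 replicate 3. Leaving out a library of the group outside a comparison left its lost regions unchanged and was no check. With peaks ranked by fold enrichment the second call was also lost, at 5.75% against 1.38% (Fisher's exact test, adjusted p = 0.433).

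Between Res499 and B16_IFNg, 56 regions were gained in Res499 and 84 were lost, 10.8% of the 1291 regions called in exactly 3 of the 6 libraries. Gained regions lay at the ends of Hook1 (chromosome 4, 95966820 to 95967634), Fbxo46, Pde8a (chromosome 7, 81212694 to 81213650) and Ckap4 (chromosome 10, 84533666 to 84534412). Another lay inside the transcription factor gene Mef2c, 19672 bp from its end (chromosome 13, 83523689 to 83524905). Lost regions lay at the ends of Mcm10, a DNA replication factor (chromosome 2, 5012165 to 5012997), Enox2 and Eef2, a translation elongation factor (chromosome 10, 81176103 to 81177077). Others lay inside Fat1 (chromosome 8, 44980006 to 44980741) and Foxk1 (chromosome 5, 142430880 to 142431464). In the full lists 47 of the 56 gained regions had a peak in B16_IFNg and 67 of the 84 lost ones had a peak in Res499. The Pde8a region had one in 3 B16_IFNg libraries, the Hook1 and Mef2c regions in 2, and the Fbxo46 and Ckap4 regions in 1. The Eef2, Fat1 and Foxk1 regions had one in 2 Res499 libraries and the Mcm10 and Enox2 regions in 1. Eef2 also kept a peak within 1 kb of a gene end in 2 Res499 libraries of the equal-length lists and in 3 of the full lists. Of the gained regions 62.5% and of the lost regions 52.4% lay near coding gene ends (Fisher's exact p = 0.297). That gap changed direction without Res499 replicate 1, to -14.1 percentage points (Fisher's exact p = 0.00973), and without Res499 replicate 2, to -8.58 points (Fisher's exact p = 0.120). It passed the threshold in its first direction without B16_IFNg replicate 1, at 27.0 points (Fisher's exact p = 1.83e-06), and without B16_IFNg replicate 2, at 37.3 points (Fisher's exact p = 4.59e-11). It also passed under the lenient rule, at 12.2 points (Fisher's exact p = 0.000350), with 4607 peaks, at 17.3 points (Fisher's exact p = 0.0404), and ranked by fold enrichment, at 17.9 points (Fisher's exact p = 0.0431). With a library left out, its group needs fewer calls than the other group. The shifts seen on leaving out a library cannot be told apart from that change in the rule.

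**Figure D2:**
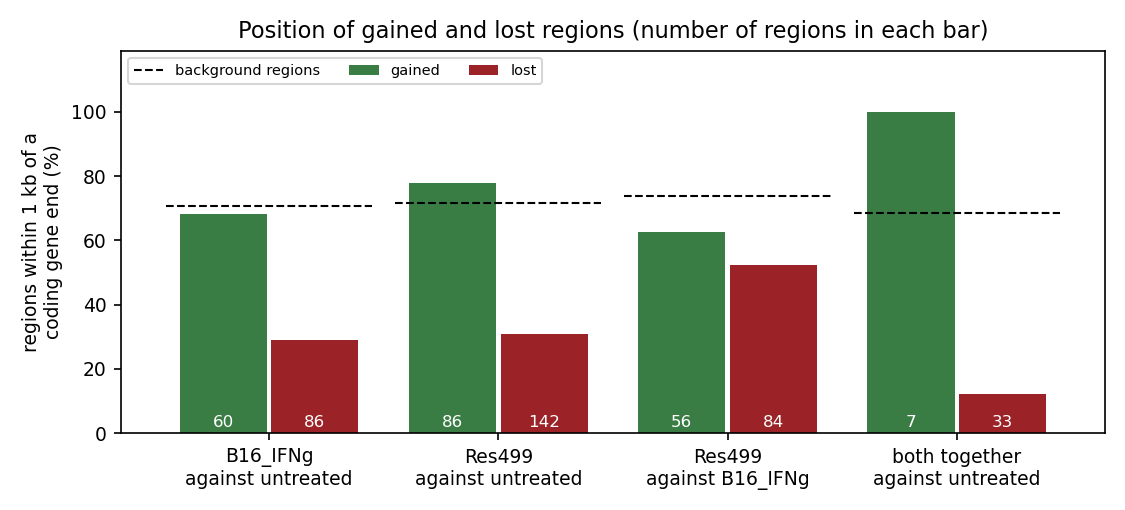
Share of gained and lost regions within 1 kb of a coding gene end (vertical axis, %) in each comparison, with the number of regions in each bar and the background share as a dashed line. Lost regions lie at 29.1%, 31.0% and 12.1% in the 3 comparisons with B16_untreated, below the background in each. Background regions have calls in at least 3 libraries. For both groups together a gained region needs 6 calls and a lost one 3.

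B16_IFNg and Res499 together were set against B16_untreated to find changes common to interferon exposure and resistance. Only 7 regions were called in all 6 of these libraries and in none of B16_untreated, and 33 showed the opposite pattern. The 7 gained regions all lay within 1 kb of a coding gene end: Hectd4, Dennd1b (chromosome 1, 138963045 to 138964213), Crim1 (chromosome 17, 78199789 to 78200995) and Ap4e1 (chromosome 2, 127008584 to 127009059). The others were Ift81, a component of ciliary transport (chromosome 5, 122614094 to 122614585), Cd2ap (chromosome 17, 42876123 to 42876802) and Hrob (chromosome 11, 102248719 to 102249301). The lost regions were mostly distal, with 4 of 33 near a coding gene end (Fisher's exact test over regions, p = 1.77e-05). A gained region here needs calls in 6 libraries and a lost one in 3, so the rule itself makes the sets unlike. Other choices of 3 libraries, under the same rule, gave gaps of up to 80.8 points in size, against the real 87.9. The lost regions included sites 2754 bp from 1700057G04Rik (chromosome 9, 92360630 to 92361146) and 47216 bp from Prune2 (chromosome 19, 17271179 to 17271597). Others lay 19570 bp from Rngtt (chromosome 4, 33289917 to 33290730) and inside Prkar1b (chromosome 5, 139051315 to 139051812). In the full lists all 7 gained regions had a peak in 3 B16_untreated libraries, and 26 of the 33 lost ones had a peak in B16_IFNg or Res499, these 4 among them. In the long class, with 2 libraries on each side, the shares near gene ends were 54.4% of gained and 43.8% of lost regions. In the short class, with 4 libraries against 1 of B16_untreated, they were 76.1% and 16.7%. Over all deposited peaks, 1 region was gained and 411 were lost (Fisher's exact p for position = 0.104), and lists of 4607 peaks gave 5 and 10 (Fisher's exact p = 0.282). The gap of 87.9 points was 51.8 without B16_untreated replicate 3 (Fisher's exact p = 4.80e-05) and 57.4 without Res499 replicate 3 (Fisher's exact p = 8.59e-05). Without Res499 replicate 2 and with longer lists it was 32.8 points, with 46.7% of gained regions near gene ends (Fisher's exact p = 0.0258). Both comparisons use the same untreated libraries, and unchanged groups simulated against them shared 3.47 gains (range 0 to 9) and 6.37 losses (range 2 to 14) on average. The simulated lists were shorter, with 41.65 gained and 52.9 lost regions in 1 comparison. Scaled by the product of the list lengths, the simulated overlaps come to 10.3 gains, above the 7 counted, and 27.8 losses, against 33. Independent lists would share 0.330 and 0.781. The untreated libraries were too few to be split into sets of at least 2, so part of any excess may come from the shared controls.

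None of the 17 gene lists, covering 407 genes, passed an adjusted p of 0.05 in the share of members with a peak within 1 kb of either gene end (exact permutation test, Benjamini-Hochberg), and 1 had an unadjusted p under 0.05. That list was antigen presentation by MHC class I, at 40.9 ± 0% of 22 genes in B16_untreated (SD, n = 3), 53.0 ± 6.94% in B16_IFNg (SD, n = 3) and 48.5 ± 2.62% in Res499 (SD, n = 3), with an exact p of 0.0357 for both groups together and an adjusted p of 0.607. The share was higher in 6 of 6 libraries than in any of B16_untreated. In the long class B16_IFNg and Res499 were both at 45.5%, and in the short class B16_IFNg was at 59.1% and 54.5% and Res499 at 50% in both libraries. Of its members, named after their values were seen, H2-K1, a classical class I heavy chain, was called in 0 B16_untreated, 2 B16_IFNg and 1 Res499 libraries, Nlrc5, the class I transactivator, in 0, 2 and 0, and H2-D1 in 0, 1 and 2, while Psmb10 was called in 2, 0 and 0. The gene counts above are those of the equal-length lists. The difference changed sign over all deposited peaks, to -11.4 percentage points (exact p = 0.274). There 1 of the 22 genes had a peak in more B16_IFNg libraries than B16_untreated ones and 5 in fewer. For Res499 these numbers were 1 and 8.

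Interferon-stimulated genes had a peak in 22.5 ± 3.32% of 46 members in B16_untreated (SD, n = 3), 21.0 ± 11.2% in B16_IFNg (SD, n = 3) and 19.6 ± 3.77% in Res499 (SD, n = 3; exact p = 0.750 for both together). Targets of interferon gamma stood at 10.5%, 11.4% and 10.5% of 35 genes (exact p = 1), and components of interferon signalling at 69.8%, 69.8% and 66.7% of 21 genes (exact p = 0.810). Ligands of inhibitory receptors were at 19.7%, 18.2% and 18.2% (exact p = 0.619), costimulatory ligands at 11.1%, 16.7% and 11.1% (exact p = 0.524) and MHC class II presentation at 16.7%, 14.3% and 16.7% (exact p = 1). Genes of the pigment cell lineage had a peak in 31.0 ± 5.97%, 35.6 ± 7.96% and 35.6 ± 5.27% of 29 members (SD, n = 3 each; exact p = 0.357). Neural crest and dedifferentiation genes had one in 28.6%, 27.6% and 27.6% (exact p = 0.786) and NF-kB targets in 22.7%, 26.7% and 25.3% (exact p = 0.417). Cell cycle genes had one in 70.7%, 69.3% and 76.0% (exact p = 0.810) and housekeeping genes in 72.4%, 70.1% and 73.6% (exact p = 1). Over all deposited peaks, whose number differs between groups, the pigment list stood at 69.0%, 48.3% and 46.0% (exact p = 0.0119, adjusted p = 0.202) and the interferon-stimulated list at 50%, 36.2% and 24.6% (exact p = 0.0476, adjusted p = 0.202).

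**Figure D3:**
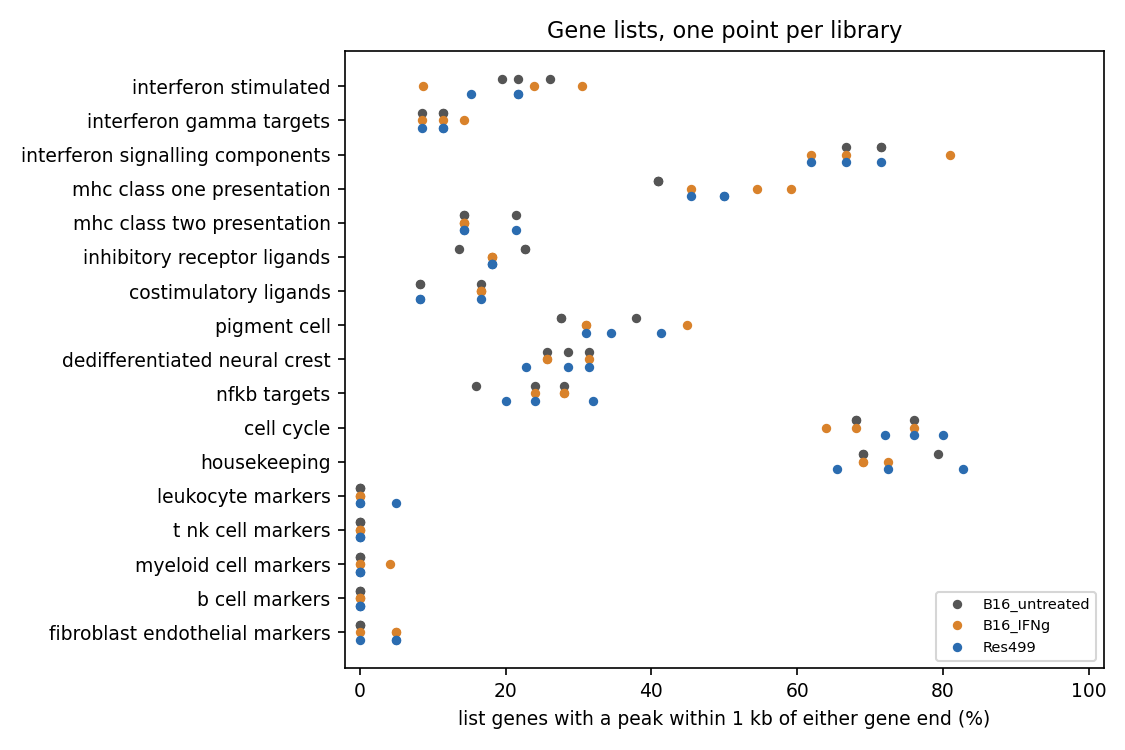
Percent of the genes of each list with a peak within 1 kb of either gene end (horizontal axis), 1 point per library, over the equal-length lists. For MHC class I presentation the B16_untreated libraries all lie at 40.9% and the other 6 between 45.5% and 59.1%.

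Of the 13 genes chosen in advance, 4 had a peak in all 9 libraries. These were the immune ligand gene Cd274 (chromosome 19, 29362107 to 29388095) and Irf1, a transcription factor induced by interferon (chromosome 11, 53770014 to 53778374). The others were B2m, the light chain of MHC class I (chromosome 2, 122147687 to 122153082), and Mitf, a regulator of melanocytes (chromosome 6, 97807002 to 98021360). Tyr, an enzyme of melanin synthesis, had one in 1 library of each group. Lgals9, Irf7 and Ifit1 were called in 0, 1 and 0 libraries of B16_untreated, B16_IFNg and Res499, and Mx1, Sox10, Tnfrsf14 and Ptprc in none. In the full lists Lgals9, which encodes a galectin that binds an inhibitory receptor, had a peak in 3, 1 and 0 libraries, Tyr in 3, 3 and 1, Mx1 in 2, 1 and 0, Irf7 in 1, 2 and 0, Ifit1 in 1, 1 and 0, and Sox10 in 1, 0 and 0, while Tnfrsf14 and Ptprc had none. A gene without a peak was not detectably open at this depth, which does not show closed chromatin.

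Markers of other cells that a sorted tumour suspension could hold had few peaks in the equal-length lists and more in the full lists, and those named here were chosen after their values were seen. No marker of T and natural killer cells (25 genes) or of B cells (10 genes) had a peak in the equal-length lists. General leukocyte markers had 1 gene with a peak, Spi1 in 1 Res499 library, myeloid markers had S100a8 in 1 B16_IFNg library, and fibroblast and endothelial markers had Col1a1 in 2 B16_IFNg and 1 Res499 libraries and Eng in 1 Res499 library. In the full lists S100a8 had a peak in 2 libraries of each group and Col1a1 in 3 B16_untreated, 3 B16_IFNg and 1 Res499 libraries. There the T cell factor Tcf7 had a peak in 3, 1 and 1 libraries, Cd4 in 1, 2 and 0, Spi1 in 2, 1 and 1, and Eng in 2, 0 and 1, in the same order of groups. Cr2 had one in 1 Res499 library, and Arhgdib, Coro1a and Pdgfrb had one in 1 B16_untreated library each. The exact p for B16_IFNg and Res499 together in the equal-length lists was 0.167 for the fibroblast and endothelial list and 1 for the other 4.

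No enrichment of differential regions near the genes of a list was detected. Of 136 Fisher's exact tests, 0 passed an adjusted p of 0.05 and 2 had an unadjusted p under 0.05, both for the single Lcp2 site among leukocyte markers. In each test 0 or 1 differential region belonged to the list, so enrichment could hardly have been detected.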

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

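Ranking by fold enrichment, leaving out Res499 replicate 2 with longer lists, all settings for the position of gained and lost regions, and leaving out libraries in the chromosome tests were chosen only after the results were seen. Among the main results, 132 values under another setting stayed: tests kept their direction and side of the threshold, and counts stayed close to the main count. A further 66 counts moved away from it, and of the tests 4 turned, 5 newly passed the threshold and 7 no longer passed it. For counts neither direction nor threshold was checked. Of the 88 named regions, counted once per comparison, 88 stayed called in all of one group and none of the other when peaks up to 250 bp apart were merged, 53 with ranking by fold enrichment, 35 where a peak had to cover 50% of the region, 11 over all deposited peaks and 9 with 4607 peaks per library. Depth limits all of these, since a region without a peak is one not detected. Except where the construction shows it, the cause was not tested.

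Gained and lost regions of B16_IFNg against B16_untreated numbered 776 over all deposited peaks, 97 with 4607 peaks per library, 425 with 50% cover, 840 under the lenient rule and 18 when absent from the full lists of the other group. Ranked by fold enrichment they numbered 223. For Res499 against B16_untreated they numbered 1218, 136, 628, 1099 and 47 under the first 5 of these settings, and 497 without Res499 replicate 2 and with longer lists. For Res499 against B16_IFNg they numbered 867 under the lenient rule, 26 when absent from the full lists and 351 with the longer lists. For both groups together against B16_untreated they numbered 412 over all deposited peaks, 15 with 4607 peaks per library, 159 with 50% cover, 261 under the lenient rule and 7 when absent from the full lists. Shared gains numbered 1 over all deposited peaks and 2 with 50% cover, and shared losses 411 over all deposited peaks, 10 with 4607 peaks per library and 157 with 50% cover. The lenient rule raises counts and the full lists lower them by construction. Chromosome tests past the threshold numbered 7 under the lenient rule and 1 ranked by fold enrichment. The share of peaks near gene ends in both groups together differed by 14.4 points over all deposited peaks, whose number differs between groups (exact p = 0.0119). Ranked by fold enrichment it differed by 4.15 points (exact p = 0.0357).

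Gene list differences between both groups together and B16_untreated turned over all deposited peaks for interferon gamma targets (-3.33 points), MHC class I (-11.4), costimulatory ligands (-12.5), pigment cell (-21.8), NF-kB (-10.7), cell cycle (-9.33), leukocyte (-5.00) and fibroblast and endothelial genes (-5.83). With 4607 peaks per library they turned for interferon-stimulated genes (0.362), interferon gamma targets (-0.476), interferon signalling (9.52) and MHC class II (4.76). With a 2.5 kb window they turned for interferon gamma targets (-1.43), pigment cell (-0.575), neural crest (1.905), housekeeping (3.45) and myeloid genes (-2.78). Ranked by fold enrichment they turned for interferon gamma targets (-0.952), neural crest (5.24) and housekeeping genes (4.60). The number of libraries with a Lgals9 peak, B16_IFNg minus B16_untreated, was -2 over all deposited peaks.

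Leaving out each library in turn gave 273 to 460 regions for B16_IFNg and 370 to 640 for Res499 against B16_untreated, 329 to 404 for Res499 against B16_IFNg, 51 to 196 for both together, 14 to 56 shared gains and 37 to 140 shared losses. These counts grow because fewer libraries must be called. The calls needed then also differ between the groups, which enters the gaps in position. The within-group excess in similarity ran from -0.00141 to 0.0153 (exact p = 0.0429 to 0.568), the gap in position for Res499 against B16_IFNg from -14.1 to 37.3 points, the share of peaks near gene ends in both together from 2.36 to 3.55 points (exact p = 0.0357 to 0.179) and that of Res499 against B16_IFNg from -0.772 to 1.49 points. The difference in peak number ran from -9926 to -4762 for both together and from -3038 to 49.3 for Res499 against B16_IFNg. List differences ran from -4.20 to 0.145 points for interferon-stimulated genes, -0.476 to 0.952 for interferon gamma targets, -2.38 to 1.19 for MHC class II, -2.38 to 0.476 for neural crest and -2.76 to 2.87 for housekeeping genes.

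The replicate numbers did not clearly pair the libraries. Correlations of same-numbered libraries ran from -0.0153 to 0.0624 over 9 pairs, 0 of them over 0.1, and those of other pairs from -0.0676 to 0.0414. Of 9 libraries, 5 correlated best with their own number. Same-numbered libraries of different groups had a somewhat higher mean Jaccard index than other pairs of different groups. All libraries numbered 2 were of the short fragment class and all numbered 3 of the long class. Replicate number can therefore not be fully told apart from class, in this index or in the block. With the replicate number as a block, regions numbered 1392 for B16_IFNg and 1736 for Res499 against B16_untreated and 1396 for Res499 against B16_IFNg. In the block the difference in peak number for both groups together was -7356 and no longer past the threshold (exact p = 0.111), and that in the share of peaks near gene ends was 2.90 points and newly past it (exact p = 0.0370).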

Other observations

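The tests by other splits of the libraries, of depth, of fragment class, of X percentiles and of X regions that some Res499 library has were chosen only after the results were seen, and so were the genes of the next paragraph.

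In the equal-length lists Tnfsf9, the ligand of a costimulatory receptor, had a peak in 1 B16_untreated, 3 B16_IFNg and 3 Res499 libraries, and Icosl, another costimulatory ligand, in 3, 3 and 1. Psmb9 and Tap1, neighbouring genes of antigen processing, were each called in 2, 3 and 3 libraries, and the pigment gene Tyrp1 in 3, 2 and 0. In the full lists no costimulatory ligand had a peak in more B16_IFNg or Res499 libraries than B16_untreated ones. Of the 22 class I genes, 1 had a peak there in more B16_IFNg libraries than B16_untreated ones and 5 in fewer. For Res499 these numbers were 1 and 8. Chromosome 5 regions ranked higher by summit pileup in Res499, at a mean percentile of 51.4 ± 0.581 (SD, n = 3), than in the other 6 libraries, at 45.6 ± 1.57 (SD, n = 6), with a two-sided exact p of 0.0119, the smallest possible, and an adjusted p of 0.119 over 20 chromosomes. Chromosome 14 regions ranked lower, at 38.4 ± 0.397 (SD, n = 3) against 41.5 ± 0.870 (SD, n = 6; exact p = 0.0119, adjusted p = 0.119).

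For B16_IFNg against B16_untreated, 4 of the 10 splits of the 6 libraries gave as many gained and lost regions as the real 146, the highest other giving 210. The split along fragment class gave 202, and within classes the counts were 1026 gained and 864 lost in the long and 791 gained and 1165 lost in the short class, where 1 library stands for a group. For Res499 against B16_untreated, 1 of 10 splits reached the real 228, the highest other giving 192 and the split along fragment class 169, and for Res499 against B16_IFNg 2 of 10 reached 140, the highest other giving 185. With 10 splits a share under 0.05 cannot be reached. For both groups together, 5 of 84 choices gave as many as the real 40 regions, the highest other giving 60, so chance was not excluded.

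B16_IFNg and Res499 had fewer deposited peaks than B16_untreated. The tables argue against fragment class as the whole source, since the difference held within classes (exact p = 0.0333). The estimates gave no sign of a lower depth in Res499, at 1.07 times that of B16_untreated (two-sided exact permutation p = 0.5, with overlapping libraries). In each class every Res499 library was deeper than every B16_untreated library but had fewer peaks. The depths were 11.1 against 10.8 and 9.78 in the long class, and 10.9 and 8.68 against 8.14 in the short class. The order of 11.1 and 10.8 rests on the division by the shortest peak, since the recovered backgrounds were 1.89 and 2.00. Lower depth is therefore not excluded in Res499. For B16_IFNg, at 0.855 times that of B16_untreated and with overlapping libraries, lower depth stays open. Weaker enrichment of reads in open regions may contribute: summit pileup over background at common regions was 33.1 ± 16.5 in B16_untreated, 21.9 ± 4.24 in B16_IFNg and 17.4 ± 3.35 in Res499 (SD, n = 3 each; exact p = 0.0595). That p pools the fragment classes. In each class every B16_untreated library lay above all others. In the long class the values were 19.98 and 27.8 in B16_untreated, against 17.04 in B16_IFNg and 15.3 in Res499. In the short class they were 51.7 in B16_untreated, against 24.6 and 24.2 in B16_IFNg and 21.3 and 15.7 in Res499. This order within classes was not tested. A difference of the cells themselves stays open and was not tested.

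Regions lost in both groups lay away from gene ends and regions gained in both lay near them, by 51.8 points without B16_untreated replicate 3, 57.4 without Res499 replicate 3 and 32.8 without Res499 replicate 2 and with longer lists. In the equal-length lists 1 of 84 choices of 3 libraries, the real one, reached its gap of 87.9 points (highest other 80.8). With 4607 peaks 21 of 84 reached the real 40 points, and with all deposited peaks 4 of the 43 choices that give a gap reached 89.8. Chance is not excluded, since the gap was chosen after it was seen, rests on 7 gained regions and was matched by other choices in the other lists. Enrichment of reads stays open. Pileup over background and the share of peaks near gene ends had r = -0.261 (permutation p = 0.560) over 9 libraries. Their rho was -0.15 (permutation p = 0.708), and r was 0.620 (permutation p = 0.142) without the 2 farthest. These values pool the fragment classes. In each class the library with the highest pileup had the lowest share. These were B16_untreated replicate 3 (27.8, 65.9%) in the long class and B16_untreated replicate 2 (51.7, 67.2%) in the short class. The lowest pileup went with the highest share in the long class (Res499 replicate 3, 15.3, 68.8%). It did not in the short class (Res499 replicate 2, 15.7, 69.6%). The relation within classes was not tested. Fragment class cannot be told apart either, because the share of peaks near gene ends differed by 2.31 points within classes (exact p = 0.1). In the long class the gap kept its direction for both groups together (54.4% of gained and 43.8% of lost regions, 2 libraries on each side). It turned there for each group alone, where 1 library was set against 2 and a gained region needed fewer calls than a lost one. A biological difference was not tested apart from these.

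Chromosome X regions were called in B16 and missing in Res499 more often than others. Drop-out of weak regions stays open. At 45 X regions called in every B16 library, 72.6% of Res499 calls were present, against 91.6 ± 2.59% (SD over draws) at rank-matched autosomal regions. A share of 0.0001 of 10000 random draws was as low, the smallest they can give. At the 40 of these X regions that some Res499 library has, the value was 81.7% against 93.0 ± 2.39% (SD over draws), with a share of 0.00020 as low. X was singled out by its missing Res499 calls in these same lists, and the draws resample regions and not libraries. The draws describe these libraries and cannot settle drop-out. In each fragment class the Res499 shares of used peaks on X lay below those of the other libraries, by -0.476 points within classes (exact p = 0.025). This p uses the same lists that singled out X and makes no allowance for that choice. It therefore describes these libraries and cannot settle fragment class. A lower X copy number in Res499 is a hypothesis that stays open. The pileup ratio of X to autosomes was 0.969 times that of the other libraries at 20 regions called in all 9 (exact p = 0.560), which selects regions that Res499 kept. With uncalled regions counted as lowest the mean X percentile was 27.7 ± 2.88 (SD, n = 3) against 32.9 ± 4.19 (SD, n = 6; exact p = 0.0714). That p pools the fragment classes. In the long class the percentile was 26.3 in Res499, against 26.4 and 32.3 in B16_untreated and 31.8 in B16_IFNg. In the short class it was 25.9 and 31.0 in Res499, against 38.8 in B16_untreated and 32.4 and 35.9 in B16_IFNg. The order within classes was not tested. Altered accessibility of X in Res499 was not separated from copy number.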
